A study of Mus musculus with 10 samples.

How the data were processed

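The samples were 10 RNA libraries, 5 labelled as liver metastasis lines and 5 as primary tumour, made by polyA selection from cultured cells per the labels' protocols. The authors deposited 1 table of FPKM values with a column for each library, which held 48516 genes with an identifier and 35 further lines without one, and the latter were left out. The submitters' processing notes name Salmon, edgeR and the mouse build mm8, with no version or role. The program that made the FPKM values is not given in the sources used here. The gene identifiers and loci of the table were compared with GENCODE M21, an annotation of GRCm38. Of the identifiers, 40599 were found there with the same version, and 62.0% of these had the same locus and 99.97% lay inside the locus given. Coordinates are therefore given for GRCm38, with positions counted from 1, and not for mm8. The reads and their alignment were not analysed here. Where a symbol occurred more than once, it was used for the row with the highest mean.

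FPKM values are not counts, so no count test was run. The depth was estimated from 232 single-exon genes of at least 3000 bases, in which the smallest step between values gives what 1 fragment is worth. The estimate was between 24.0 and 30.4 M fragments in 9 libraries and 15.8 M in metastasis 25. The FPKM sum of metastasis 25 was above that of each of the other 9, which was at most 653161. Its value of 1 fragment was also the highest, so a scaling of this library to something other than its own total, or shorter transcripts, would each give this, and neither was tested. In the former case its depth estimate would be too low. The 10 most abundant genes took between 6.66% and 12.4% of the FPKM sum. An exact 0 can be a failed estimate in this table: in 6 libraries, 21 values were 0 where the other 9 libraries all had at least 1 FPKM. Genes that share reads with near-identical copies, such as the haemoglobin, immunoglobulin and Ins1 and Ins2 genes, and genes that overlap others are uncertain, since the assignment of such reads is not stated. No 2 libraries held identical values.

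Samples were grouped by the cell type label, which gives group and tumour number. The primary and metastasis samples share their numbers. Deviations from the group means correlated between samples of the same number at 0.39 (number 25), 0.86 (35), 0.89 (36), 0.68 (38) and 0.23 (72), so the numbers were taken to pair the samples. Metastasis 25 correlated best with primary 72, metastasis 35 with primary 36 and metastasis 72 with primary 25, so the pairing is not exact in the data. A fit with the number as a block was an alternative, and its value stands beside a result only where it changed the call.

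Genes with at least 1 FPKM in at least 5 of the 10 libraries were kept, 13152 in all. The values were used as log2(FPKM + 1), with no further scaling, so fold changes of low genes are understated. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend) and Benjamini-Hochberg adjustment at 0.05, with statmod 1.5.0 for the random-effect block. Of 35 gene lists fixed before the data were examined (cell types, signalling, metabolism, stress and matrix), 32 had at least 5 kept genes and were tested with camera at a preset correlation of 0.01. Of their 670 genes, 666 were found under the listed symbol and 2 under an older one. As an alternative, camera was run with a correlation estimated for each list. That form also takes its degrees of freedom from the residuals between libraries (8 in the main fit, 4 with the block) and not from the genes. It therefore calls lists less readily even at the same correlation, and a lost call does not measure correlation alone. Each metastasis line was compared with the primary group in a model with 1 coefficient per line, in which the spread comes from the primary libraries alone. The spread within the groups was compared by a exact permutation of labels over all splits after removal of the group means. A further 8 marker lists were added after the data had been seen, for erythroid cells, T cells, B and plasma cells, macrophages, neutrophils, skeletal muscle, Y-linked genes and the urea cycle. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

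The rule for named genes was fixed at the same time as the lists. It takes the largest changes past the threshold and, where fewer than 5 genes in a direction pass, the 8 with the smallest unadjusted p, passing over unnamed gene models. It adds up to 4 members of each list described, the largest called differences of each line, and 11 genes of this tumour type. Genes named for single libraries, single pairs or within subsets of the numbers were chosen after their values were seen.

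Alternatives chosen in advance were another pseudocount (0.1), other expression minimums, median ratio scaling, quantile normalization, the block as a fixed or random effect, omission of each library in turn, no intensity trend, sample weights, a fold threshold, and other list tests. Comparisons within numbers 35 and 36, within numbers 25, 38 and 72, and with single zeros replaced by the group mean were added after the data had been seen.

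The limma fits, camera at the preset correlation, the permutation of the spread and the comparison of single lines were checked on simulated data. Camera with an estimated correlation, the other list tests and Dixon's test of outlying libraries were not. With the spread of the real libraries over 13152 genes, the fit with the block recovered 28.4%, 82.1% and 97.0% of genes planted at 1, 2 and 4 on the log2 scale. The fit within numbers 35 and 36 recovered 49.3%, 79.1% and 95.5%, and the fit within numbers 25, 38 and 72 recovered 1.49%, 44.8% and 80.3%. Genes without a planted change that were called numbered 7 over all libraries and 6 with the block. They numbered 9 within numbers 35 and 36 and 4 within numbers 25, 38 and 72. A cell cycle list planted at -1 was called by camera in all 4 simulated comparisons, with 0 of the 31 other lists called. The permutation of the spread fell under 0.05 in 6.67% of 60 simulations with equal spread. These simulations draw genes independently, whereas genes of 1 list move together in the real libraries.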

Results

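Polyadenylated RNA was sequenced from 10 libraries of a mouse pancreatic cancer model in the FVB strain. Ink4a.1, a pancreatic cancer cell line, was injected into the pancreas of mice, and lines were grown from the liver metastases that followed. The labels give 5 libraries of liver metastasis lines, numbered 25, 35, 36, 38 and 72, and 5 libraries labelled primary tumour with the same numbers. The series design names metastases from 4 mice, whereas 5 metastasis numbers are labelled. According to the labels all samples were cell cultures at 90% confluence. The table gave 1 FPKM value (fragments per kilobase of transcript, scaled to the depth of the library) per gene and library for 48516 genes. The depth read from the smallest steps of the values was between 15.8 M and 30.4 M fragments, lowest in metastasis 25, if each library was scaled to its own total. The labels do not say whether the primary samples came from separate animals or were repeat cultures of 1 line, so p-values measure the spread between these samples, which may be technical in part.

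Before the groups were compared, the libraries were examined for transcripts of other cell types, since lines grown from liver can carry host cells. The 4 libraries of numbers 35 and 36 held almost no transcripts of leukocytes. Lyz2, the lysozyme of macrophages and granulocytes, was between 0.61 and 1.05 FPKM in these libraries and between 345 and 2727 FPKM in the 6 libraries of numbers 25, 38 and 72. C1qa, a complement gene of macrophages, was at most 0.18 FPKM in the former and between 167 and 802 FPKM in the latter. Ptprc, which encodes the pan-leukocyte antigen CD45, was at most 0.02 FPKM against 4.34 to 46.1 FPKM. Of the 15 leukocyte markers, 13 were higher in each of the 6 libraries than in any of the 4. The haemoglobin gene Hbb-bs was between 8.31 and 18065 FPKM in the 6 libraries and at most 0.18 FPKM in the 4. Both the primary and the metastasis library of each of the numbers 25, 38 and 72 held these transcripts.

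Markers of organs differed from library to library. Metastasis 25 held 9850 FPKM of Alb (serum albumin) and 5432 FPKM of Apoa1 (apolipoprotein A-I), both made by hepatocytes. Primary 72 held 436 FPKM of Alb and 604 FPKM of Apoa1, more than metastasis 72, with 139 and 56.4 FPKM. Metastasis 38, labelled a liver metastasis, held 0.16 FPKM of Alb and 1978 FPKM of the skeletal muscle actin Acta1. Its value for the muscle creatine kinase Ckm was 959 FPKM, against 69.4 FPKM in primary 72 and at most 0.22 FPKM in the other 8 libraries. Primary 25 held 5163 FPKM of the insulin gene Ins2 and 216 FPKM of the acinar chymotrypsinogen gene Ctrb1. In the other 9 libraries Ins2 was at most 8.02 FPKM and Ctrb1 at most 6.06 FPKM. Igkc, the immunoglobulin kappa constant region, was 1834 FPKM in primary 25 and at most 47.1 FPKM elsewhere. S100a9, a calcium-binding protein abundant in neutrophils, was 6727 FPKM in metastasis 25 and at most 26.7 FPKM in the other 9 libraries.

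**Figure D1:**
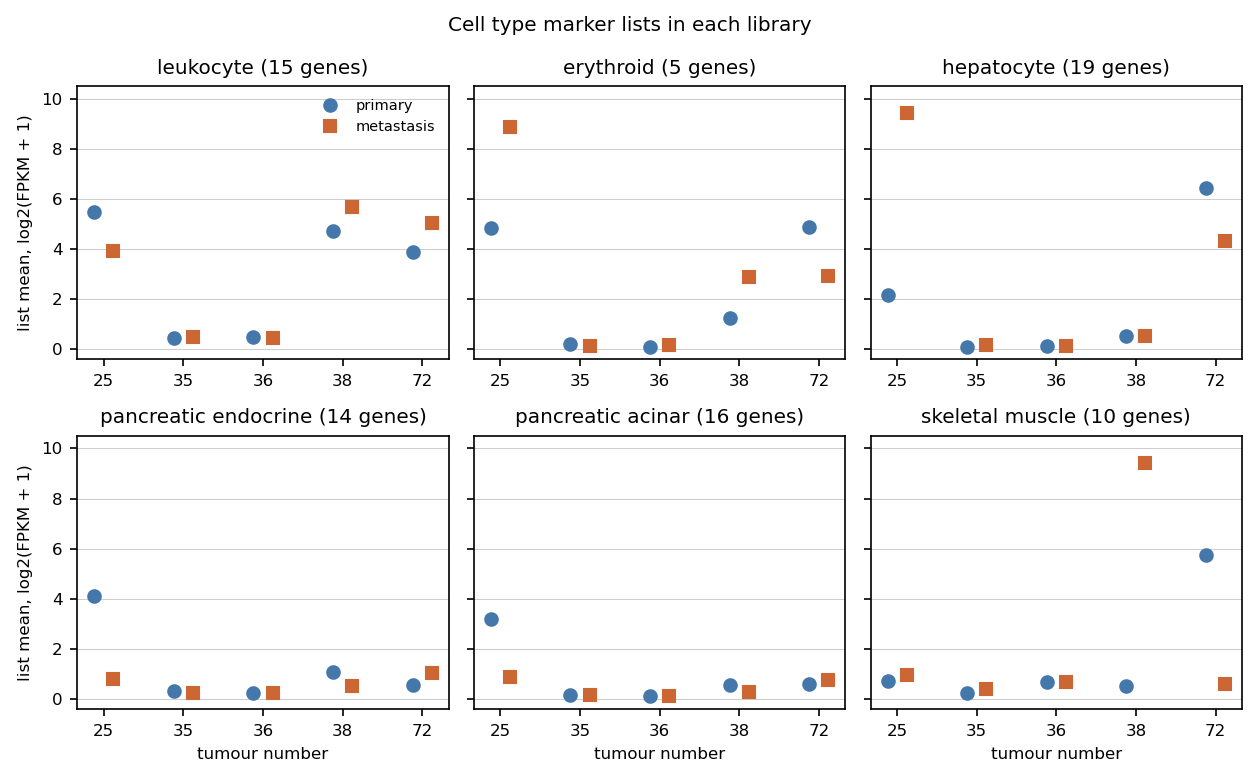
Mean log2(FPKM + 1) of the genes of 6 cell type marker lists (vertical axis) in each primary library (circles) and metastasis library (squares), by tumour number (horizontal axis). The leukocyte list lies between 0.44 and 0.49 in the 4 libraries of numbers 35 and 36 and between 3.89 and 5.66 in the other 6, while the hepatocyte list peaks at 9.44 in metastasis 25 and the skeletal muscle list at 9.42 in metastasis 38.

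Some epithelial genes followed the same division, 9 of the 25 on the epithelial list. Cdh1, which encodes E-cadherin, was at most 0.29 FPKM in the 4 libraries of numbers 35 and 36 and between 1.90 and 8.71 FPKM in the other 6. Epcam, an epithelial adhesion molecule, was at most 0.06 FPKM against 0.86 to 15.2 FPKM. The mesenchymal filament gene Vim was abundant in all 10 libraries, between 1443 and 6667 FPKM, and highest in metastasis 36. The keratin gene Krt8 was also present throughout, between 16.3 FPKM in metastasis 38 and 325 FPKM in primary 72.

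The first principal component of log2(FPKM + 1) carried 62.4% of the variance and parted the 4 libraries of numbers 35 and 36 from the other 6. The second, with 16.6%, set metastasis 25 apart. Neither parted primary from metastasis. Across genes, the 4 libraries of numbers 35 and 36 correlated with each other at between 0.976 and 0.989, with primary 36 and metastasis 35 the closest. Primary 25 and metastasis 72 correlated at 0.969, above every other pair within the numbers 25, 38 and 72. Genes are not independent replicates, so these correlations describe the libraries only.

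**Figure D2:**
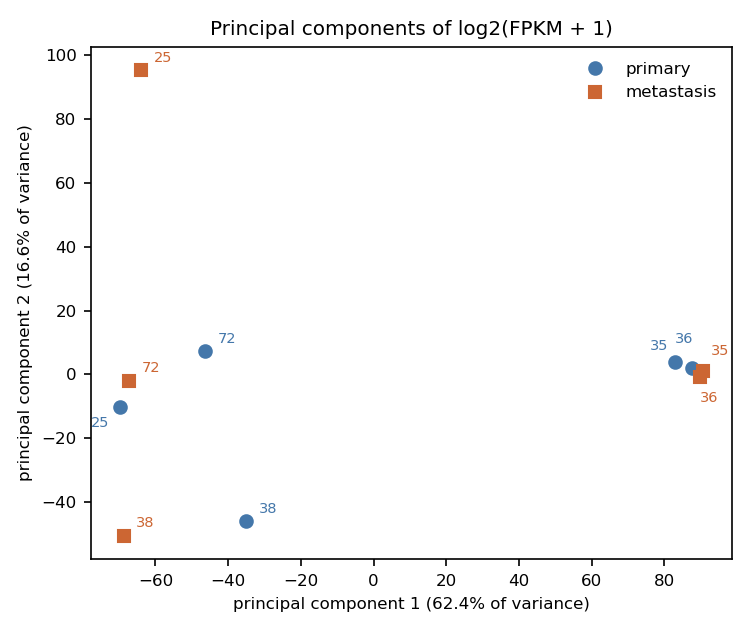
Principal components 1 (62.4% of variance, horizontal axis) and 2 (16.6%, vertical axis) of log2(FPKM + 1) over 13152 genes, with 1 point per library, labelled by its tumour number. The 4 libraries of numbers 35 and 36 lie together at the right whether primary (circles) or metastasis (squares), and metastasis 25 lies alone at the top.

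The main comparison asked which genes differ between the metastasis lines and the primary samples. The homeobox gene Msx3 (ENSMUSG00000025469.10, chromosome 7, 140046157 to 140049089, GRCm38) had a mean of 4.30 ± 2.43 FPKM in metastasis and 11.5 ± 5.83 FPKM in primary libraries (SD, n = 5 each). Its log2 fold change was -1.23 (SE 0.44), and it was lower in all 5 pairs, by between 0.78 and 1.74 on the log2 scale. The DNA replication and repair genes Lig1 (DNA ligase 1, -0.63, SE 0.22), Pold1 (the catalytic subunit of DNA polymerase delta, -0.54, SE 0.20) and Ung (uracil-DNA glycosylase, -0.71, SE 0.24) were also lower in every pair. Agreement over all 5 pairs is weak support by itself, since 310 genes were higher and 289 lower in all 5 pairs, fewer together than the 822 expected by chance. Among genes with higher values, Atf4, a transcription factor of the integrated stress response, was 261 ± 17.6 FPKM in metastasis and 206 ± 19.0 FPKM in primary libraries (log2 fold change 0.34, SE 0.15). Gadd45b, a stress-induced gene, had a log2 fold change of 0.80 (SE 0.36). Both were higher in all 5 pairs. None of these differences passed the threshold.

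With limma and Benjamini-Hochberg adjustment over 13152 genes, 0 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.9998. At an unadjusted p under 0.05 there were 31 genes, 8 higher and 23 lower in metastasis, where 658 would be expected by chance. With the tumour number as a block the count was also 0, with 208 genes at an unadjusted p under 0.05. The 5 metastasis values lay above all 5 primary values for 9 genes and below them for 4. Chance would give 104 (0.794% of genes) for libraries without the division above. The other genes with the smallest unadjusted p, none past the threshold, were Cbr3, Sorbs2, Rgs16, Sned1, Als2cl and Zfp622 among the higher ones, with log2 fold changes between 0.47 and 1.23. Among the lower ones they were Ndp, Ifitm1, Arhgef39 and Cracr2b, between -1.46 and -0.55. In simulated data with the spread of these libraries, the same limma test recovered 10.4% of genes changed by 1 on the log2 scale. It recovered 64.2% of those changed by 2 and 92.4% of those changed by 4. The simulated noise was independent between libraries and genes, without the division of the real libraries, so these shares may not hold for them.

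Genes named in advance for this tumour type did not pass the threshold either (limma adjusted p = 0.9998 for each). The log2 fold change was -0.05 (SE 0.44) for the tumour suppressor Trp53. It was 0.27 (SE 0.28) for Smad4, the shared mediator of TGF-beta signalling, and 0.37 (SE 0.42) for Myc. For Cdh1 it was 0.18 (SE 0.80), for Vim 0.08 (SE 0.46) and for Epcam -0.14 (SE 1.02). For Ptprc it was 0.19 (SE 1.22), and for the proliferation marker Mki67 -0.44 (SE 0.67). Alb and Cdkn2a were under the expression minimum. Cdkn2a, which encodes p16INK4A and p19ARF, was listed at 0 in metastasis 25 and in all 4 libraries of numbers 35 and 36, and lay between 0.10 and 3.35 FPKM in the remaining 5.

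As lists, proliferation and sterol synthesis genes had lower means in the metastasis libraries, a difference that depended on the test (for both, adjusted p = 0.974 with an estimated correlation). All 25 cell cycle genes had a lower mean in metastasis, the list mean was lower in all 5 pairs, and the mean log2 fold change was -0.50. Examples were E2f1, a transcription factor of S phase entry (-0.46, SE 0.21), the replicative helicase genes Mcm7 (-0.37, SE 0.19) and Mcm3 (-0.73, SE 0.42), and the DNA topoisomerase gene Top2a (-0.80, SE 0.52). Of 21 cholesterol biosynthesis genes, 20 were lower, again in all 5 pairs as a list, with a mean of -0.26. Among them were Dhcr7 (-0.70, SE 0.43), Cyp51 (-0.58, SE 0.62) and the prenyl transferase gene Fdps (-0.39, SE 0.41). No single member of any list passed the threshold over all genes or adjusted over the list alone.

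In limma's camera test, with a preset correlation of 0.01 and adjustment over 32 lists, 6 lists were called. These were cell cycle (adjusted p = 1.67e-11) and cholesterol biosynthesis (0.0110), both lower (adjusted p = 0.974 with an estimated correlation), and 4 higher lists. Nuclear-encoded oxidative phosphorylation genes had a mean of 0.16 (20 of 25 higher, adjusted p = 0.00149, and 0.974 with an estimated correlation), with Ndufs3 at 0.41 and Atp5c1 at 0.46. This list was higher in 3 of 5 pairs, most in pair 25 (0.51), and its mean was 0.054 without metastasis 25, the library richest in hepatocyte and erythroid transcripts. Ribosomal protein genes had a mean of 0.16 (24 of 29 higher, adjusted p = 0.0110, and 0.974 with an estimated correlation), with Rps14 at 0.62 and Rpl8 at 0.36. Immediate early and stress genes had a mean of 0.25 (17 of 20 higher, adjusted p = 0.0250, and 0.974 with an estimated correlation), with Atf3 at 1.37 and Nr4a1 at 0.53. Mitochondrially encoded genes had a mean of 0.088 and a median of 0.40 (6 of 9 higher, adjusted p = 0.0250, and 0.740 with an estimated correlation), with mt-Cytb at 0.53, while mt-Co1 was listed at 0 in metastasis 25. With single zeros replaced by the group mean, the mean of this list was 0.42 (adjusted p = 1.38e-04). With an estimated correlation none of the 32 lists was called. That form of camera also rests on 8 residual degrees of freedom. The estimated correlation was 0.83 for cell cycle and 0.81 for cholesterol biosynthesis. For the mitochondrially encoded list it was 0.013, near the preset, so the lost call of that list does not come from its genes moving together. In an exact two-sided permutation of the 10 list means, which ignores the pairs, the p was 0.373 for cell cycle and 0.651 for cholesterol biosynthesis. An exact sign-flip of the 5 pair differences gave 0.0625 for both, the smallest value that 5 pairs can give. With the tumour number as a block a further list was called, Wnt targets and pathway genes (mean -0.30 over the 9 of 20 genes above the expression minimum, adjusted p = 0.0238, against 0.105 without the block). In that blocked fit no list was called with an estimated correlation (adjusted p = 0.480 for the Wnt list). That form has 4 residual degrees of freedom there. The estimated correlation of the Wnt list was -0.052, below the preset, so its lost call does not come from its genes moving together. The mean of these 9 genes was lower in all 5 pairs, whereas the mean of all 20 was higher in metastasis in pairs 36 (0.74 against 0.61) and 72 (2.08 against 1.71).

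The cell cycle list lay between 6.11 and 6.23 in the 4 libraries of numbers 35 and 36 and between 3.65 and 5.18 in the 6 libraries that held leukocyte transcripts. Its difference between metastasis and primary was largest in pair 72 (-1.53 on the log2 scale) and smallest in pair 36 (-0.045). With the preset correlation the list kept an adjusted p under 0.05 without any 1 library (with all libraries, adjusted p = 0.974 with an estimated correlation). Its mean moved to -0.17 without metastasis 72 (adjusted p = 0.0103). It moved to -0.32 without primary 35 and also without primary 36, to -0.78 without metastasis 35 and to -0.80 without metastasis 36. The cholesterol list lost its call without primary 35 (mean -0.0064), primary 36 (-0.085), metastasis 25 (-0.071) and metastasis 72 (0.011). The oxidative phosphorylation list lost it without primary 38 (0.094) and metastasis 25 (0.054). The ribosomal list lost it without primary 25 (0.17), primary 35 (0.12), primary 36 (0.14), primary 38 (0.11) and metastasis 25 (-0.016). The immediate early list lost it without primary 35 (0.20), primary 36 (0.15), primary 72 (0.16), metastasis 38 (0.20) and metastasis 72 (0.0011). With all libraries and no expression minimum it also lost its call (mean 0.25, camera adjusted p = 0.108). The mitochondrially encoded list lost it without primary 25 (0.087), primary 38 (-0.055), metastasis 35 (0.066), metastasis 36 (0.035) and metastasis 72 (-0.026).

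**Figure D3:**
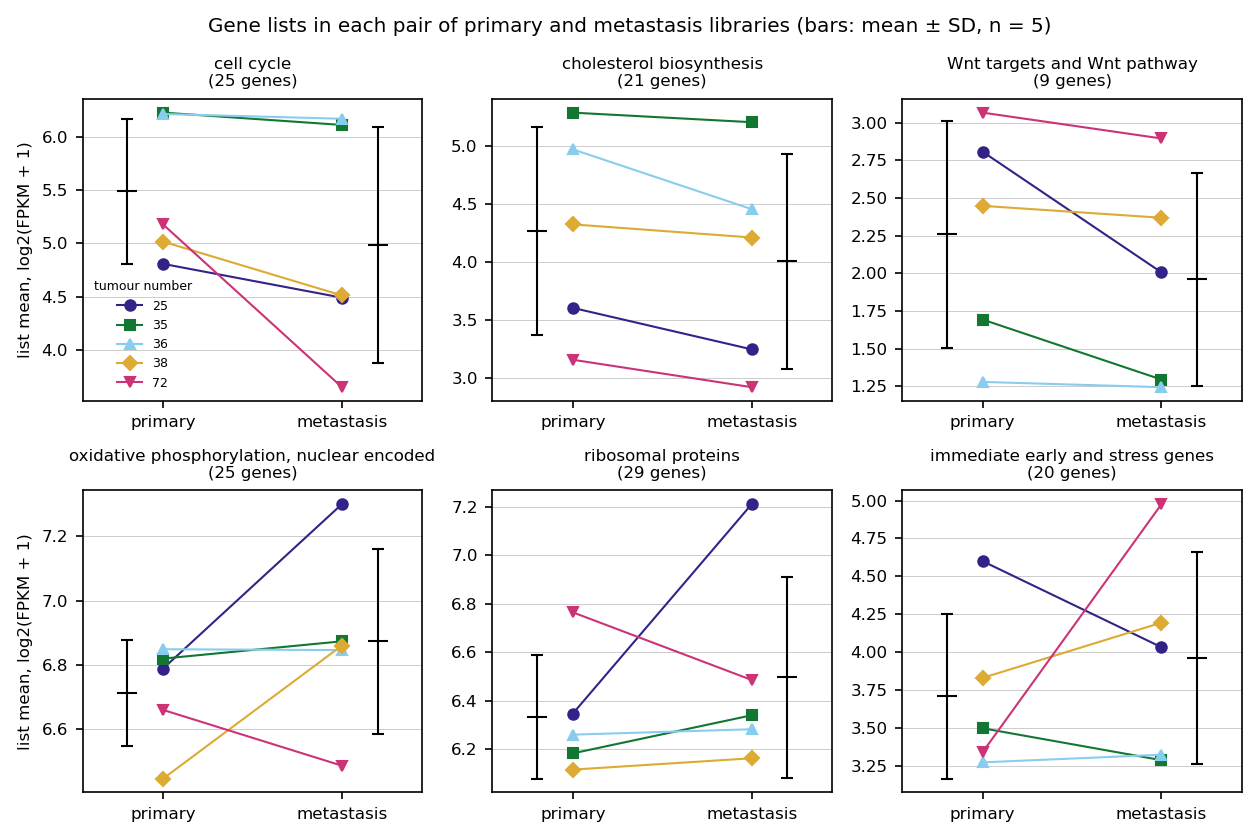
Mean log2(FPKM + 1) of the genes above the expression minimum of 6 gene lists (vertical axes, each with its own range) in the primary and metastasis library of each tumour number, joined by a line, with the mean ± SD of each group of 5 beside the points. The cell cycle, cholesterol biosynthesis and Wnt lists end lower on every line, most steeply for the cell cycle list in pair 72, whereas the other 3 lists move both ways.

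The remaining 26 lists were not called, with mean log2 fold changes between -0.30 and 0.22 and adjusted p between 0.105 and 0.909. They included the epithelial (-0.041) and mesenchymal (-0.032) lists and the classical (0.047) and basal-like (-0.057) subtype lists of pancreatic cancer. Among signalling lists the means were -0.0073 for MAPK output, 0.013 for TGF-beta targets, 0.024 for the Notch pathway, 0.019 for p53 targets, 0.12 for YAP/TEAD targets, 0.13 for inflammatory cytokines and NF-kB targets and -0.30 for the Wnt list. The fatty acid synthesis list had a mean of -0.14 over 13 of its 14 genes (adjusted p = 0.263), with its desaturase gene Scd2 at -0.64 (SE 0.34). The leukocyte list, over the 12 of 15 genes above the expression minimum, had a mean of 0.20 with opposite pair values, -1.32 in pair 25 and 1.11 and 1.21 in pairs 38 and 72.

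The libraries of numbers 35 and 36 held almost no leukocyte, erythroid or hepatocyte transcripts and replicated closely. The groups were therefore also compared within them, a choice made after seeing the data. Fibroblast genes were not absent there: the mean of the fibroblast list lay between 2.46 and 3.34, highest in primary 35. The median SD of log2 values was 0.098 between the 2 primary and 0.11 between the 2 metastasis libraries, against 0.50 and 0.60 over all 5 of each group. The growth factor gene Hbegf was 109 ± 1.35 FPKM in these metastasis and 62.5 ± 2.83 FPKM in these primary libraries (SD, n = 2 each). The cell surface proteoglycan gene Gpc4 was 1.44 ± 0.021 against 7.69 ± 0.72 FPKM (log2 fold change -1.83, SE 0.12). Msx3 had a log2 fold change of -1.20 (SE 0.10) here and of -1.26 (SE 0.30) within numbers 25, 38 and 72. None passed the threshold (limma adjusted p = 0.722, 0 genes), with 800 genes at an unadjusted p under 0.05 against 658 expected by chance.

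Within numbers 35 and 36, 1 list was called with camera, cholesterol biosynthesis (mean -0.30, 20 of 21 genes lower, adjusted p = 0.0349). With the block 5 lists were called, adding fatty acid synthesis (-0.19) and p53 targets (-0.20) as lower and YAP/TEAD targets (0.25) and class I antigen presentation (0.43) as higher. With an estimated correlation no list was called (smallest adjusted p = 0.975 without and 0.946 with the block). That form of camera has 2 residual degrees of freedom there, and 1 with the block. It could hardly call any list at this size, so it decides nothing here. Cell cycle genes were not called there (mean -0.080, 15 of 25 lower, adjusted p = 0.107 with the block). Within numbers 25, 38 and 72 the cell cycle mean was -0.78 (adjusted p = 6.62e-21 with the preset and 0.784 with an estimated correlation), and the cholesterol list was not called (mean -0.24, adjusted p = 0.111). With the block the cholesterol list was called there (adjusted p = 0.0246), as was the ribosomal list (0.0314, against 0.111 without), and with an estimated correlation neither was (0.942 for both). Called there both without and with the block, and not over all libraries, were hypoxia and glycolysis (lower, mean -0.29, adjusted p = 0.0480 and 0.0281) and integrated stress response genes (higher, 0.22, 0.0480 and 0.0414). With an estimated correlation neither was called (0.906 without and 0.942 with the block). That form of camera has 4 residual degrees of freedom in these libraries, and 2 with the block, so these lost calls do not measure correlation alone. In these 6 libraries the limma count was 0 genes, with 145 at an unadjusted p under 0.05. Atf3, a stress-induced transcription factor, had a mean of 26.4 against 5.21 FPKM there (n = 3 each; log2 fold change 2.09, SE 0.36, limma adjusted p = 0.999). The claudin gene Cldn6 was 1.76 ± 2.32 against 11.3 ± 1.39 FPKM (SD; log2 fold change -2.46, SE 0.56, same adjusted p).

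Each metastasis line was also set against the 5 primary libraries. Line 25 differed in 2 genes. Asl, the argininosuccinate lyase of the urea cycle (ENSMUSG00000025533.15, chromosome 5, 130011258 to 130029247, GRCm38), was 408 FPKM against 16.6 ± 2.65 FPKM (SD, n = 5; log2 difference 4.55, SE 0.35, limma adjusted p = 0.0343). Asl did not pass with single zeros replaced by the group mean (limma adjusted p = 0.0686) or under quantile normalization (0.0658). The other was mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, listed at 0 in this library and at 5999 ± 1434 FPKM in the primary libraries (limma adjusted p = 3.58e-04). An exact 0 can be a failed estimate, and 11 genes of this library were at 0 where all other 9 libraries had at least 1 FPKM. Lines 35, 36, 38 and 72 differed in 0 genes, with 70, 74, 368 and 310 genes at an unadjusted p under 0.05, against 1686 in line 25. A lone line is assumed here to vary as the primary libraries do. Their spread takes in both numbers 35 and 36 and the unlike others, so a count of 0 does not show a line like the primary samples. Without primary 25, the count was 28 genes in line 25 and 17 in line 72. Without primary 35, 36 or 38 it was 1 gene in line 25.

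Pair by pair, the number of genes that differed by more than 1 on the log2 scale was smallest in pair 36 (99 higher and 115 lower in metastasis) and pair 35 (150 and 224). It was 975 and 411 in pair 38, 1371 and 1556 in pair 72 and 1569 and 1712 in pair 25. In pair 36 the matrix and contractile genes Postn (25.3 against 0.16 FPKM), Tnc (16.6 against 0.07 FPKM) and Tagln (28.4 against 2.13 FPKM) were among the highest. In pair 35 the matrix proteoglycan genes Lum (0.13 against 30.3 FPKM) and Dcn (0.97 against 19.3 FPKM) were among the lowest. Both are on the fibroblast list and were high in primary 35 only among these numbers. In both libraries of number 36 Lum was at most 0.23 and Dcn at most 3.92 FPKM. A single pair has no replicate, and these are the most extreme values of each pair.

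The metastasis libraries were not shown to vary more among themselves than the primary libraries. The median log2 ratio of the SD in metastasis to that in primary libraries was 0.25, and 69.5% of genes had the wider SD in metastasis. An exact two-sided permutation of the labels, which ignores the pairs, gave p = 0.151, where the smallest possible value is 0.00794. Without metastasis 25 the ratio was 0.12.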

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

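All tests of explanations in this part were chosen after the result was seen, except the depth test of metastasis 25. Within each group of 5 libraries, the gap between the most extreme library and its neighbour was set against the whole range, for 246 groups of values. In 18 groups the gap was above Dixon's 95% critical value, where independent groups not chosen by their values would give 12.3. Asl, mt-Co1, Als2cl and Cracr2b were included because of their values in the tests above. The skeletal muscle list was added after the data had been seen, and Ckm and Ins2 were counted beside lists that hold them. The 18 groups are therefore not shown to exceed chance. In metastasis 25 these were the FPKM sum (0.836 of the range), Asl (0.852), Als2cl (0.716) and mt-Nd4 (0.823) as the highest, and mt-Co1 (0.977) as the lowest value of the metastasis group. In metastasis 38 they were the skeletal muscle list (0.940) and its member Ckm (0.985) as the highest and Krt8 (0.727) as the lowest. In metastasis 72 it was Cdkn2a (0.737), the highest. In primary 25 they were the pancreatic endocrine (0.781) and acinar (0.842) lists, Ins2 (0.743) and the Wnt inhibitor gene Notum (0.808), all highest. In primary 72 they were the skeletal muscle list (0.910), Ckm (0.961) and mt-Nd4 (0.779) as the highest, and the MAPK output list (0.823) and Cracr2b (0.835) as the lowest.

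Transcripts of blood and immune cells stood in the 6 libraries of numbers 25, 38 and 72, and organ transcripts in some of them, although the labels describe cell cultures. Organ lists were low in primary 38 (hepatocyte 0.54, skeletal muscle 0.50, pancreatic acinar 0.57, pancreatic endocrine 1.10). Macrophages alone, which can persist in culture, would not bring other lineages: of 21 erythroid, T cell, and B and plasma cell genes, 12 were higher in each of the 6 libraries than in any of the 4 others. A single common source of foreign RNA or reads would keep 1 ratio, whereas the macrophage list minus the erythroid list spanned 8.36 on the log2 scale over the 6 libraries, from -3.69 in metastasis 25 to 4.67 in primary 38. RNA of cells of the host animals is a candidate explanation: the 4 libraries without these cells held Y-linked Ddx3y (3.77 to 20.1 FPKM) and at most 0.17 FPKM of Xist, and Xist was at least 46.1 FPKM in both libraries of numbers 38 and 72 and at most 1.10 FPKM in both of number 25. This would need tissue, or cultures with host cells, in place of pure lines, and the labels do not say which, so it remains a hypothesis.

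Metastasis 25 stood apart, with 1686 genes at an unadjusted p under 0.05 in limma against the primary libraries. A lone library has no spread of its own, so these numbers, here and below, describe its distance from the primary libraries in units of their spread. Scaling between libraries is argued against, since 1434 genes were at that level under quantile normalization, and 1273 of the 1686 were among them in the same direction. The adjusted count was 1 under that normalization, against 2. Its lower estimated depth is argued against by the 3288 genes with the highest means, of which 17.1% were at that level, against 12.8% of all genes. RNA of liver cells may contribute: the other 4 urea cycle genes (Cps1, Otc, Ass1 and Arg1) were all highest in this library (4 of 4), and 2 of them also belong to the hepatocyte list. This is weak support from Arg1, at 778 FPKM against 545 FPKM in metastasis 72 and at least 156 FPKM in all 6 libraries with leukocyte transcripts, and from Otc, at 3.73 against 2.03 FPKM in primary 72. No biological difference between this line and the others was tested beyond this.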

How the results depend on the processing

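The count of 0 genes between metastasis and primary held under all 25 alternatives. In the alternatives run for them, 22 or 23 per gene, 0 of the 49 named genes reached an adjusted p under 0.05, and 38 kept their direction. The number of called lists was 0 with an estimated correlation and 0 with fry, which tests a list against no change and not against other genes. It was 1 within numbers 35 and 36 only, and between 5 and 11 when each library was left out in turn (5 without primary 38, 11 without metastasis 72). With the replicate block it was 7, and over all 10 libraries the block changed no call other than that of the Wnt list. Within numbers 25, 38 and 72 the block brought the number of lists from 6 to 8, and within 35 and 36 from 1 to 5. The correlation of libraries with the same number was 0.55 as a random effect. The count for single lines was 1263, 179, 173, 1395 and 486 for lines 25, 35, 36, 38 and 72 with no expression minimum, where genes at or near 0 in all primary libraries have almost no spread. For line 25 it was 1 under quantile normalization, 1 against the primary libraries of numbers 25, 38 and 72 only, and 0 with single zeros replaced by the group mean, which removes the 0 of mt-Co1 and ends the call of Asl (adjusted p = 0.0686). Leaving out each primary library gave between 1 and 28 genes for line 25 and between 0 and 17 for line 72. The spread ratio kept its direction and side of the threshold, between 0.12 and 0.35.

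Directions of named genes reversed without a call on either side, and those of 4 called lists reversed with their call lost. The cause was not tested. Within numbers 35 and 36, with and without the block, the log2 fold change was 0.19 for Trp53, 0.058 for Mcm3, 0.16 for Top2a, -0.066 for Uqcrc2 and -0.61 for Hspa1a. When each library was left out in turn, the values lay between -0.30 and 0.17 for Trp53, between -0.11 and 0.44 for Vim and between -0.74 and 0.39 for Epcam. They lay between -0.23 and 0.58 for Cdh1, between -0.62 and 0.77 for Ptprc, between -0.77 and 0.052 for Mki67 and between -0.044 and 0.77 for Hspa1a. Of the called lists, the mitochondrially encoded list had a mean of -0.033 with a pseudocount of 0.1 and -0.050 under quantile normalization, and between -0.055 and 0.26 when each library was left out. The immediate early list had a mean of -0.080 within numbers 35 and 36, with and without the block. When each library was left out, the ribosomal list lay between -0.016 and 0.27 and the cholesterol list between -0.56 and 0.011. DESeq2 was planned only for counts and was not run. The depth is an estimate, and genes near 1 FPKM rest on few fragments in metastasis 25, the library with the lowest estimate.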

Other observations

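The tests of explanations in this part were chosen after the result was seen, except the splits that count gene lists. The 8 marker lists added after the data had been seen had these means of log2(FPKM + 1), which describe the libraries and no group. The T cell list was highest in metastasis 38 (4.26) and primary 25 (3.58) and lowest in metastasis 25 (0.36), below the 0.66 to 0.71 of numbers 35 and 36. The B and plasma cell list was 5.35 in primary 25 and between 0.80 and 2.54 in the other 5 libraries of numbers 25, 38 and 72. The macrophage list was between 5.05 and 6.78 in these 6 libraries, with all 9 genes above their level in the 4 others. The neutrophil list was 6.54 in metastasis 25 and between 2.14 and 2.90 in the other 5. The erythroid list was 8.87 in metastasis 25 and 1.26 in primary 38, and the Y-linked list was between 1.34 and 2.80 in all 10 libraries. H2-Ab1, an MHC class II gene of antigen-presenting cells, was 1552 FPKM in metastasis 38 and 3.36 FPKM in metastasis 25.

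Msx3 differed between metastasis and primary by -1.25, -1.18, -1.22, -1.74 and -0.78 on the log2 scale in pairs 25, 35, 36, 38 and 72. With the tumour number as a block its SE was 0.19 and its unadjusted p in limma was 3.29e-04, and it did not pass adjustment (limma adjusted p = 0.999). It was picked here after its values were seen.

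The library labelled primary 72 had a higher hepatocyte list (6.42) than the library labelled metastasis 72 (4.31), and metastasis 72 correlated more closely with primary 25 (0.969) than with primary 72 (0.872). In pair 72 the FPKM of Rps21 was 4.73 in the primary and 2223 in the metastasis library, a log2 difference of 8.60. The difference in Rps21 was 0.64, 0.15, -0.23 and 0.52 in pairs 25, 35, 36 and 38. Whether the low value of Rps21 in primary 72 is a failed estimate was not tested, and it is no evidence on the labels. An exchange of the labels of number 72 was not excluded. It would turn the cell cycle difference of that pair (-1.53, the largest of the 5), so that the list would be lower in 4 pairs and its mean difference over the 5 pairs would be 0.11 in place of -0.50. The direction of the cell cycle list therefore rests on these labels. The cholesterol list would also be lower in 4 pairs and not in 5, with its mean difference at -0.17 in place of -0.26. The immediate early list, at 1.64 in pair 72 and between -0.57 and 0.36 in the others, would have a negative mean. So would the mitochondrially encoded list, at 0.24 in pair 72 and between -0.61 and 0.60 in the others.

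The cell cycle list was lower in metastasis in all 5 pairs. Scaling between libraries is argued against, since the mean log2 fold change was -0.55 under quantile normalization, with the call at the preset correlation kept while the ribosomal list lost its own. That call itself does not hold with an estimated correlation (adjusted p = 0.974). A lower share of tumour cells with an unchanged mix of other cells would raise the markers of every other cell type. Over all genes of each list, the hepatocyte list was 7.28 higher and the leukocyte list 1.55 lower in pair 25. In pair 72 the leukocyte list was 1.13 higher and the skeletal muscle list 5.14 lower. The lists moved apart by at least 6.27 on the log2 scale in both pairs, so the mix was not the same. A lower share together with a changed mix is not excluded by this in either pair. In pair 38 the lists moved apart by 8.94, but none was lower beyond its error. A lower share cannot be told apart from slower growth in any of these pairs. A lower tumour share, a change in which host cells were present, and slower growth of the metastasis lines may each still contribute. With leukocyte, erythroid and hepatocyte lists at most 0.49 in pairs 35 and 36, the cell cycle list was not called there (mean -0.080).

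Other splits of the libraries were drawn to ask whether chance could give the counts. For genes the real count was 0, so each split had to give at least as many, and these counts test nothing. Of 100 splits of the 10 libraries into 5 and 5, the real one included, this was 100, and the highest other count was 3963 genes, in a split that left all libraries of numbers 35 and 36 on 1 side. That split shows a structure of the samples that is unrelated to the groups. For the called gene lists, 84 of the 100 splits gave at least the real 6, with 24 as the highest other count, so chance is not excluded for the number of lists. Only 16 splits part all 5 pairs, too few for a share under 0.05. With the block, 12 of them gave at least the real 7 lists (highest other 17), and the gene count was 0 in all 16. The 10 splits of numbers 25, 38 and 72 into 3 and 3 are also too few. There 9 gave at least the real 6 lists (highest other 19), and the highest gene count was 332, against the real 0, a level that all 10 reach by definition.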
